A study of Mus musculus with 40 samples.

How the data were processed

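RNA from 5 brain regions of mice with threonine or alanine at position 92 of the type 2 deiodinase, aged 8 to 10 weeks per the labels, was measured on 40 microarrays, 4 for each of 10 groups. The deposited table holds log2 signals that the authors obtained with RMA, per the submitters' processing notes, with the software version not given in the sources used here. RMA corrects background, normalizes between arrays and summarizes probes, so array medians lay between 6.12 and 6.32 before any further step, and no scaling was added. Of 28846 rows, 6640 were control rows, 19572 had 1 gene symbol in the platform annotation, 0 had several and 2634 transcript rows had none. All 19572 named rows matched the GRCm38.p6 gene table.

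For each of 19505 genes the row with the highest mean over the arrays was kept, which mattered for 55 genes. Genes above the 30th percentile of all values (log2 4.60) on at least 4 arrays entered the tests, 14978 in all. No array was identical to another. A linear model with a mean for each of the 10 groups was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend), with 30 residual degrees of freedom. Contrasts were Ala minus Thr in each region, their mean, an F-test of whether they differ, and each region against the mean of the other regions. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and between regions also at an absolute log2 difference of at least 1. Adjusted p-values of genes in the text are from these limma fits.

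Before the data were examined, 37 gene lists were fixed. Of their 676 entries, 612 were on the array and 588 were measured, and the 35 lists with at least 5 measured genes were tested with camera at a preset correlation of 0.01, adjusted over the lists of a contrast. The calls were repeated with an estimated correlation and with fry. A list score of an array is the mean of its genes after centring on the region. Named genes followed a rule fixed at the same time: up to 10 called genes per direction, the 5 smallest p where fewer than 5 passed, Dio2 and 8 other genes of hormone action and protein folding always, 4 members of each called list, and 8 higher and 4 lower genes per region.

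The 50 measured genes on each side of Dio2 were compared with all others by a two-sided Fisher test. The steps were tested on simulated data with known differences. Of genes changed by 1 log2 unit in the amygdala and in the striatum, 64% and 76% were called, of genes changed by 0.5 units 2% and 10%, and of genes changed by 2 units 100%. In the average over regions 88% of genes changed by 0.5 units were called. Each simulated comparison held 50 changed genes of each size, up to 4 units, with noise independent between genes. In them, 140 genes were called in the amygdala and 152 in the striatum, against 18 and 12 in the real comparisons. The adjusted threshold was therefore stricter in the real comparisons, and these shares are likely too high for them. The number of arrays limits this precision.

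Alternatives covered scaling, the filter on dim genes, the rows tested, the estimate of the spread, array weights, thresholds, tissue scores and a residual component as covariates, the set test, and leaving out each array or region. The labels give no batch, date or animal for an array, and no pairing of arrays was used in the comparisons. After the results of the comparisons were seen, arrays with the same place in the order of label numbers were linked across regions in exploratory fits and splits.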

Results

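Gene expression was measured on microarrays in 5 brain regions of mice that carried either threonine or alanine at position 92 of the type 2 deiodinase, the enzyme encoded by Dio2 that converts thyroxine to the active thyroid hormone T3. The regions were amygdala, cerebellum, hippocampus, prefrontal cortex and striatum. Each of the 10 combinations of region and genotype had 4 arrays, 40 in all, and the number of arrays limits the precision of every value. After dim genes were left out, 14978 genes were tested. Differences between genotypes are given as log2 Ala minus Thr with the standard error of the limma fit, so a positive value means a higher level in the Ala arrays. The labels do not tie an array to an animal, so p-values measure only the spread between these arrays, which may be technical. The median of the negative control rows lay between 5.73 and 6.35 on the log2 scale across arrays, and genes with levels near or below that range were close to the background of the array.

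The first question was whether the level of Dio2 itself, and of genes that respond to thyroid hormone, differed between genotypes. Dio2 differed by 0.03 ± 0.09 (SE) averaged over regions, and its regional differences ran from -0.38 in cerebellum to 0.32 in amygdala, none past the threshold. The hormone receptor genes Thra and Thrb differed by 0.04 ± 0.11 and 0.36 ± 0.15, with adjusted p of 1.00 and 0.864. Klf9 and Hr, both induced by T3, differed by 0.07 ± 0.10 and -0.08 ± 0.08. Among 25 measured genes of the T3-induced list, 11 had a positive average difference and the list was not called (adjusted p = 0.819). In the list of 33 measured genes of the unfolded protein response, the response to misfolded protein in the endoplasmic reticulum, 22 had a positive average difference and the list was not called (adjusted p = 0.633). Adjusted over the list alone, 1 of the 33 was lower, and adjusted over all genes none was. Ddit3, a transcription factor of that response, had an average difference of -0.36 ± 0.09 that did not pass over all genes (adjusted p = 0.423).

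In the amygdala, 18 genes were called, 17 lower and 1 higher in the Ala arrays. Gpx3, a secreted glutathione peroxidase, was lower by 2.76 log2 units (difference -2.76 ± 0.38, adjusted p = 0.000152), at 8.21 ± 0.33 in Ala and 10.97 ± 0.86 in Thr (SD, n = 4). Gabrq, a subunit of the GABA-A receptor, differed by -2.29 ± 0.35, and Glra1, a glycine receptor subunit, by -2.05 ± 0.42. The neuropeptide genes Cartpt and Avp, which encode the CART peptide and vasopressin, differed by -1.51 ± 0.27 and -1.54 ± 0.30, and Scg2, a secretory granule protein, by -1.38 ± 0.22. Barhl2, a homeobox transcription factor, and Zim1, a zinc finger gene, differed by -2.04 ± 0.36 and -1.75 ± 0.29. Gpr165 and Ccdc42 differed by -1.80 ± 0.38 and -1.46 ± 0.31. Sema3e, a semaphorin that guides axons, was the gene called higher, at 1.39 ± 0.31 (adjusted p = 0.0453). Mean levels of Avp, Ccdc42 and Magel2 lay below the range of the negative control medians in both genotypes, and those of Gabrq, Glra1 and Barhl2 did so in the Ala arrays.

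**Figure D1:**
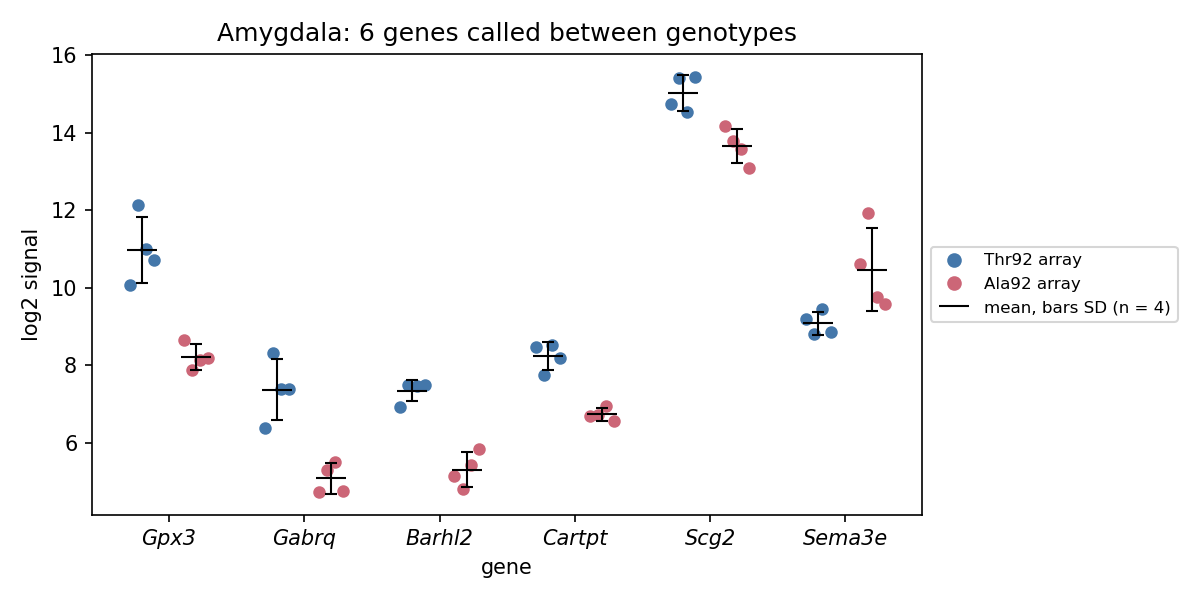
Log2 signal (vertical axis) of 6 genes called in the amygdala (horizontal axis), with a point for each array, a dash for the mean and bars for the SD of the 4 arrays per genotype. The Ala arrays lie below the Thr arrays for Gpx3 (8.21 against 10.97), Gabrq, Barhl2, Cartpt and Scg2, and above them for Sema3e.

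Marker lists that hold some of these genes were also lower, so the list p-values partly restate the calls. The amygdala marker list holds Gpx3 and Magel2. In the amygdala marker list, 11 of 13 measured genes had negative differences, with a median of -0.35 (adjusted p = 8.66e-06, and adjusted p = 0.00954 with an estimated correlation), and 4 were lower and 1 higher adjusted over the list alone against 2 lower over all genes. Magel2, an imprinted gene, differed by -1.19 ± 0.21, while Rspo2, which encodes a Wnt pathway agonist, had a difference of 1.16 ± 0.46 that did not pass (adjusted p = 0.807). In the hypothalamus marker list, 6 of 8 measured genes had negative differences (adjusted p = 0.00218, and adjusted p = 0.0233 with an estimated correlation), and the 2 that passed were Avp and Cartpt. Ala amygdala replicate 1 carried striatal transcripts, with a striatum marker score 2.00 log2 units above the mean of the region, and Ala amygdala replicate 2 had a choroid plexus score 1.59 above it. The number of called genes was 10 without Ala replicate 2, 6 without Thr replicate 6, 9 without Thr replicate 7, 9 without Thr replicate 8 and 5 with the amygdala fitted alone, and 6 of the 12 named called genes (Gpx3, Gabrq, Barhl2, Zim1, Cartpt and Scg2) passed whichever array was left out. Of these 6, Scg2 and Zim1 lost the call with the amygdala fitted alone. Barhl2, Cartpt and Zim1 lost it when the 2 amygdala arrays farthest from their groups were omitted, an alternative chosen after seeing the data. Of the 35 ways to split the 8 amygdala arrays, 4 gave at least 18 genes, and with camera on ranks the 2 lists had adjusted p of 0.0666 and 0.176.

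In the striatum, 12 genes were called, 8 lower and 4 higher in the Ala arrays. The 8 lower genes were transcripts made mainly by liver: 6 major urinary protein genes, Alb, which encodes albumin, and Fgg, a fibrinogen chain. Mup2 differed by -5.09 ± 0.68 (adjusted p = 3.09e-05), at 8.22 ± 0.65 in Ala and 13.32 ± 1.25 in Thr (SD, n = 4). Alb differed by -4.47 ± 0.60 and Fgg by -1.90 ± 0.37. Mup22, Mup19 and Mup9 differed by -5.15 ± 0.70, -5.08 ± 0.77 and -4.52 ± 0.68, and Mup3 and Mup21 by -2.06 ± 0.34 and -1.63 ± 0.34. Members of the Mup family are near-identical in sequence, so their values are uncertain as separate measurements. Higher in Ala were Cd59a, an inhibitor of complement (2.19 ± 0.42, adjusted p = 0.0119), Slc24a5 (4.93 ± 0.90 in Ala, 3.43 ± 0.17 in Thr, SD), the urea transporter Slc14a2 (0.99 ± 0.19) and Tspoap1 (0.80 ± 0.17). Mean levels of Fgg, Mup3 and Mup21 in Ala and of Slc24a5 and Slc14a2 in both genotypes were below the range of the negative control medians.

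**Figure D2:**
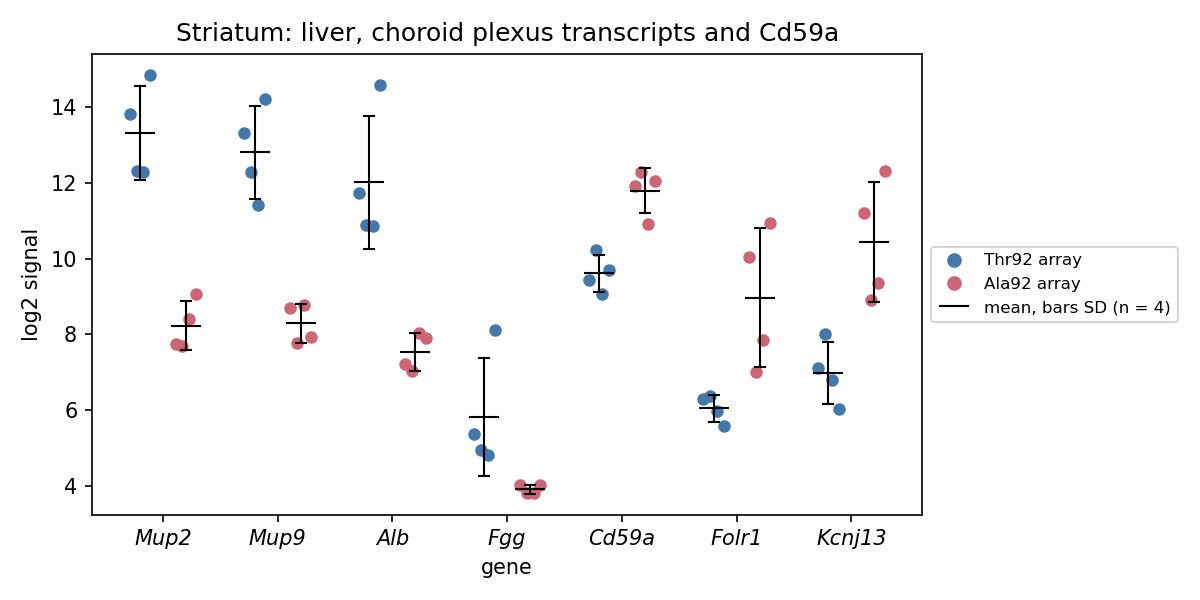
Log2 signal (vertical axis) of 7 genes in the striatum (horizontal axis), with a point for each array, a dash for the mean and bars for the SD of the 4 arrays per genotype. Mup2, Mup9, Alb and Fgg are higher in every Thr array, Cd59a is higher in every Ala array, and the choroid plexus genes Folr1 and Kcnj13 vary widely among the Ala arrays.

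Among the fixed lists, 8 were called in the striatum and 0 held with an estimated correlation. All 15 measured choroid plexus genes had positive differences, with a mean of 1.80, and 12 were higher adjusted over the list alone against 0 over all genes (adjusted p = 0.115 with an estimated correlation). Folr1, a folate receptor, and Kcnj13, a potassium channel, had differences of 2.91 ± 0.79 and 3.46 ± 1.00 that did not pass over all genes, and Ala striatum replicate 36 had a choroid plexus score 2.47 above the mean of the region. Of 22 immediate early genes, which neurons induce on activity, 19 had negative differences, with Egr4 at -0.99 ± 0.33 (adjusted p = 0.822 for the list with an estimated correlation). In the T3-repressed list, 13 of 15 measured genes had positive differences, with Col6a1 at 0.63 ± 0.23 and Cxadr at 0.50 ± 0.21 (adjusted p = 0.0811 for the list with an estimated correlation). The meninges list was called higher, with Igfbp2 at 1.69 ± 0.40, and the oxidative phosphorylation, ribosomal protein, amygdala marker and thalamus marker lists were called lower, with adjusted p of 0.822, 0.822, 0.861, 0.345 and 0.822 in that order with an estimated correlation. Ddit3 had a difference of -0.84 ± 0.20 in the striatum (adjusted p = 0.118). The gene count was 7 without Thr striatum replicate 39, 7 with the choroid plexus score as a covariate and 7 with the striatum fitted alone, and Cd59a lost its call without Ala replicate 33, 34 or 36 or Thr replicate 37 or 39, with array weights (difference 1.95) and with the choroid plexus score as a covariate (difference 1.54). Of the 12 called genes, 6 (Alb, Mup2, Mup3, Mup9, Mup19 and Mup22) passed whichever array was left out. Leaving out each of the 8 arrays in turn, Tspoap1 lost its call 7 times, Slc24a5 and Mup21 6 times, Slc14a2 5 times and Fgg 3 times. Of the 35 splits of the 8 striatum arrays, 8 gave at least 12 genes. The number of called lists was 5 without Ala replicate 33 and 3 without Ala replicate 34 or 35, and the mean difference of the oxidative phosphorylation and ribosomal protein lists turned to 0.03 and 0.04 without Thr replicate 37.

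In the hippocampus, prefrontal cortex and cerebellum no gene passed the threshold in limma, with 471, 349 and 291 genes at an unadjusted p under 0.05 against 749 expected by chance. The fit estimated the spread of a gene over all regions together. The SD of an array's deviations from its group means ran from 0.240 to 0.295 in the cerebellum and 0.281 to 0.475 in the striatum. P-values may thus be too large where arrays varied less and too small where they varied more, which limits comparing counts between regions. Fitted alone, each of these regions also had 0 called genes. The smallest p in the hippocampus belonged to Zic1, a zinc finger transcription factor, with a difference of -2.71 ± 0.55 (adjusted p = 0.250). It stood beside genes of the thalamus list, in which 11 of 12 measured genes had negative differences and 6 were lower adjusted over the list alone (adjusted p = 0.0672 with an estimated correlation). Prkcd, Calb2, Synpo2 and Tcf7l2 differed by -1.40 ± 0.31, -1.81 ± 0.45, -1.43 ± 0.37 and -1.96 ± 0.67, and Thr hippocampus replicates 23 and 24 had thalamus scores 1.78 and 1.12 above the mean of the region. The cerebellum marker, interferon, ribosomal protein and endothelial lists were also called in the hippocampus, each with adjusted p = 0.680 with an estimated correlation. The hippocampus count rose to 3 without Thr replicate 21 and 1 without Thr replicate 23.

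In the prefrontal cortex, Cd59a and Mid1 had differences of 1.51 ± 0.42 and -1.48 ± 0.40 that did not pass, and Klhl14 one of -1.45 ± 0.36. All 20 measured ribosomal protein genes had negative differences there, with a median of -0.22 (adjusted p = 0.998 with an estimated correlation), and the mean of the list turned to 0.10 when the 2 farthest arrays of the region were omitted, an alternative chosen after seeing the data. In the cerebellum, Layn had the smallest p, at -0.78 ± 0.18 (adjusted p = 0.975). Ttr, the transthyretin gene that choroid plexus expresses at a high level, differed by -4.58 ± 1.96 with an SD of 6.21 among the 4 Ala cerebellum arrays, and 13 of 15 choroid plexus genes had negative differences (adjusted p = 0.978 with an estimated correlation). The 20 ribosomal protein genes all had positive differences in the cerebellum, with a median of 0.24 (adjusted p = 0.978 with an estimated correlation).

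Averaged over the 5 regions, 3 genes were called. Cd59a was higher in Ala by 1.34 ± 0.19 (adjusted p = 9.38e-05), with positive differences in 5 of 5 regions from 0.86 to 2.19. Mid1, which encodes a ubiquitin ligase that binds microtubules, was lower, at -1.35 ± 0.18 (adjusted p = 5.50e-05), with regional differences from -1.48 to -1.14. Zfp976, a zinc finger gene, was lower at -1.01 ± 0.16 (adjusted p = 0.000489), with regional differences from -1.33 to -0.81. All 3 passed when any of the 40 arrays was left out. Entpd4 (-0.77 ± 0.17), Zfp936 (-0.56 ± 0.13), Gm15319 (0.61 ± 0.13), Kctd18 (0.39 ± 0.09), Marchf7 (0.37 ± 0.10) and Zfp369 (0.40 ± 0.10) had the same sign in all 5 regions without passing. In the T3-repressed list, 14 of 15 measured genes had positive average differences, with a median of 0.11 (adjusted p = 0.00382, and adjusted p = 0.0185 with an estimated correlation), and 0 passed singly. Cirbp, a cold-inducible RNA-binding protein, had the smallest p of the list at 0.32 ± 0.11, and the call of the list was lost with the thalamus score as a covariate (adjusted p = 0.0586), an alternative chosen after seeing the data, while its mean difference was 0.12 without and 0.10 with that covariate. The amygdala marker list was lower, with 11 of 13 negative (adjusted p = 5.02e-05, and adjusted p = 0.0185 with an estimated correlation), while calls of the thalamus and ribosomal protein lists gave adjusted p of 0.198 and 0.782 with an estimated correlation. Of 100 splits of genotype within regions, 2 gave at least 3 genes, but 77 gave at least 4 called lists, with the highest other split at 7 genes. When arrays with the same place in the order of label numbers were moved together across regions, 8 of 35 splits gave at least 3 genes.

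**Figure D3:**
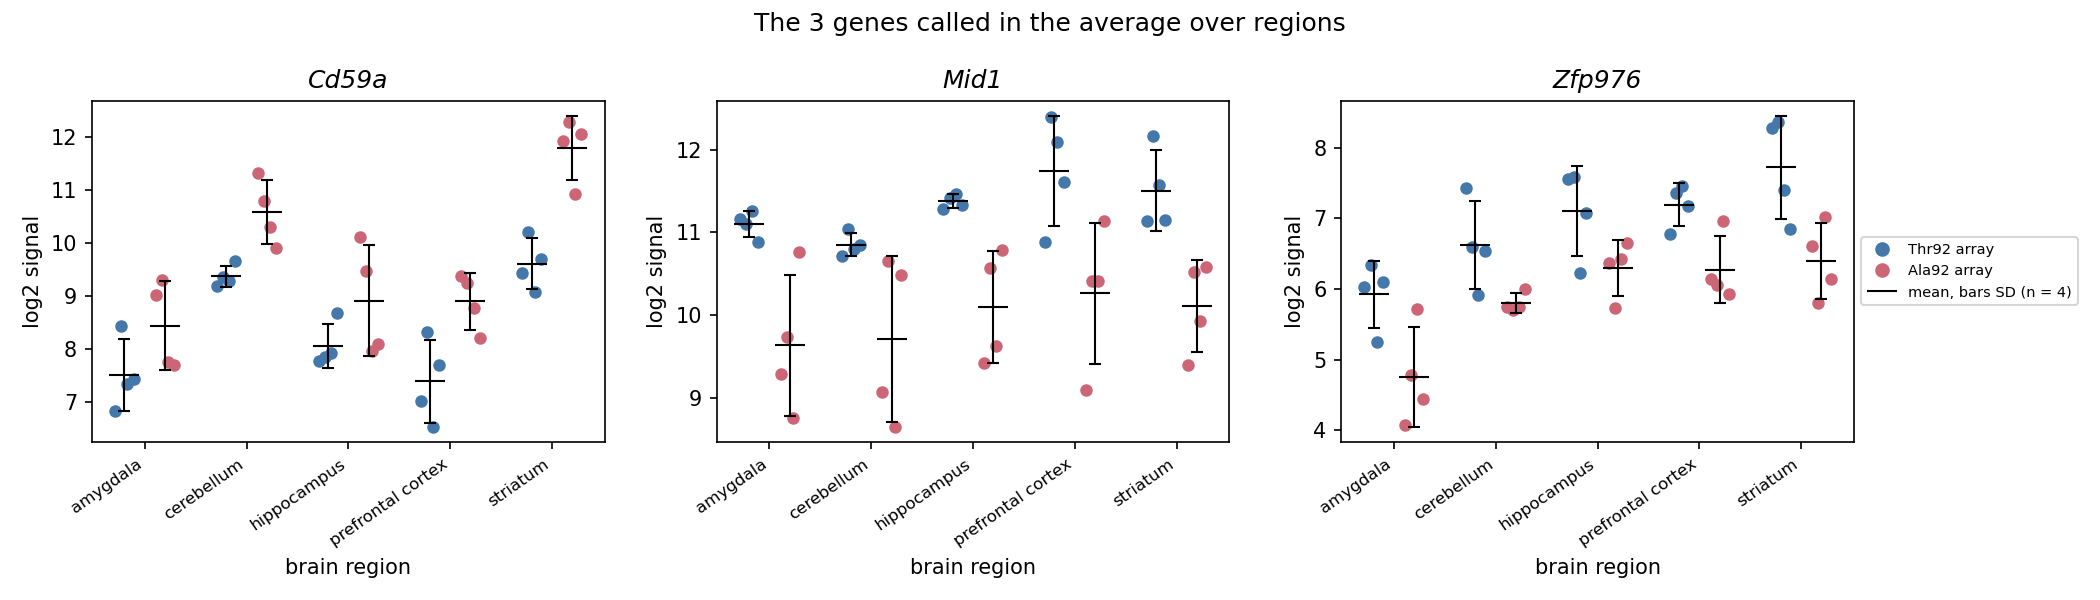
Log2 signal (vertical axis) of Cd59a, Mid1 and Zfp976 in the 5 brain regions (horizontal axis), with a point for each array, a dash for the mean and bars for the SD of the 4 arrays per group. The mean of the Ala arrays is above that of the Thr arrays for Cd59a and below it for Mid1 and Zfp976 in each of the 5 regions.

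A test of whether the genotype difference itself varied between regions called 6 genes: Mup2 and Mup22 (adjusted p = 0.0150), and Mup9, Alb, Gpx3 and Gabrq (adjusted p = 0.0232). The count was 3 without Thr amygdala replicate 6 or replicate 8, 0 without Ala striatum replicate 34 or Thr striatum replicate 40, and 0 with a robust variance estimate. Of 100 splits, 16 gave at least 6 genes. The 10 Pearson correlations across genes between regional differences had a mean of 0.0389, against a mean of -0.000510 and an SD of 0.0238 in 99 regroupings, and 6 of 100 values were as large. Genes are not independent replicates. Dio2 lies on chromosome 12 in the GRCm38.p6 annotation, and of the 100 measured genes nearest to it, 0 were called in the average and 5 had an unadjusted p under 0.05 (Fisher's exact test, two-sided, p = 1).

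The regions differed from each other far more than the genotypes did. In the cerebellum 2808 genes were called, 1302 higher and 1506 lower than the mean of the other regions. Gabra6, a GABA-A receptor subunit of granule cells, was higher by 14.00 ± 0.36, and Cbln3 and Pcp2 by 12.64 ± 0.27 and 11.26 ± 0.19, while Nrgn, which encodes neurogranin, was lower at -7.83 ± 0.18. In the striatum 1634 genes were called, 855 of them higher, among them the dopamine receptor Drd2 at 9.40 ± 0.35, the G protein regulator Rgs9 at 9.25 ± 0.31 and Drd1 at 7.71 ± 0.27, and all 16 measured striatum markers were higher. The hippocampus had 885 called genes, 535 of them higher, with Neurod6 at 5.60 ± 0.40, Cabp7 at 5.25 ± 0.22 and C1ql2 at 4.71 ± 0.25. In the amygdala 874 genes were called, 509 higher, among them the nuclear receptor Nr2f2 at 4.86 ± 0.27 and the receptor of thyrotropin-releasing hormone, Trhr, at 4.77 ± 0.28. Of 13 measured amygdala markers, 5 were higher and 1 lower in the amygdala arrays. There 7 of 15 neocortex markers were also higher, and all 16 measured oligodendrocyte and myelin genes were lower. The prefrontal cortex had 781 called genes, 491 higher, among them Cdhr1 at 5.57 ± 0.22, the tyrosine hydroxylase gene Th at 5.13 ± 0.29 and Scgn at 5.00 ± 0.22. Beside them, 11 of 15 neocortex markers and 6 of 9 olfactory bulb markers, Cdhr1 and Th included, were higher in the prefrontal cortex arrays. In the other regions the mean levels of Gabra6, Cbln3, Drd2, C1ql2, Trhr, Cdhr1 and Scgn were below the range of the negative control medians and those of Drd1 and Th within it, so the sizes of these differences depend on the background of the array and do not rank the genes.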

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

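The tests of explanations here were chosen after the patterns they bear on were seen, and those of covariation among the lower amygdala genes and of splits that move same-place arrays together were set before their own outcomes were seen, except that those splits with low and high label numbers as a covariate were added, and their rule written, later.

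The 17 lower genes of the Ala amygdala were weighed first. Scaling between arrays was not decided, since quantile normalization and median centring moved the median amygdala difference by only -0.000877 and -0.0129, so that 16 of the 17 staying past the threshold at the fewest tests nothing. A varying share of neighbouring tissue in the dissected samples may contribute, but its test does not single it out. Within groups the 17 genes varied together, with a mean pairwise correlation across the 8 arrays of 0.212. The median was -0.00653 in 1000 random sets matched on level, and the 17 genes lay at percentile 99.9 of them. The sets were matched on level alone, so genes regulated together for any other reason would also give a high value. Chance is not excluded, since 4 of the 35 splits gave as many genes (18, highest other 47), and leaving out Thr amygdala replicate 6 gave 6 genes. An effect of genotype stays open as an untested biological explanation.

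The liver transcripts of the Thr striatum were weighed second. Liver RNA carried over may be their source, since 24 further liver genes on the array, dim ones included, were lower in Ala by a mean of -0.78, the largest of 35 splits (highest other 0.727), and the 11 of them past the filter by -0.91 (highest other 0.855). A gene can pass the filter through the 4 Thr striatum arrays alone, so the value of those 11 adds no separate support. Probes shared within the Mup family are argued against as the whole cause, since Alb differed by -4.47. The liver list was written after the striatum calls were seen, and its score as a covariate left 0 of the 12 calls, which is circular because the list holds Alb, Fgg and Mup3. Chance is not excluded for the striatum, since 8 of the 35 splits gave as many genes (12, highest other 40), the count was 7 without Thr striatum replicate 39, and genotype stays open.

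Mid1, Cd59a and Zfp976, called over the 5 regions, were weighed last, and for them a stretch linked to Dio2 is argued against, since 0 of the 3 genes lie on its chromosome 12 (Mid1 on X, Cd59a on 2 and Zfp976 on 7). A stretch of strain background elsewhere in the genome cannot be told apart from an effect of genotype, since 10 of 125 neighbouring genes (8.00%) had an unadjusted p under 0.05 against 5.33% elsewhere (Fisher's exact test, p = 0.225), and too few neighbours differed to decide. Few mice behind the 20 arrays of a genotype stay open, since 8 of the 35 splits that move same-place arrays together across regions gave at least 3 genes. The highest other of these, 1262, set low against high label numbers. If a place is a mouse, that cannot be told apart from a difference between mice. With low against high label numbers as a covariate, 10 of the 34 splits that could be fitted, the real one included, gave at least 3 genes. The real split then gave 4, and 3 of the 34, the real one included, gave as many as it (highest other 7). When genotype was shuffled within each region independently, 2 of 100 splits gave at least 3 genes (highest other 7), but that shuffling ignores the structure. With place in label order as a random block, a link the design does not give, the same 3 genes were called. That fit applied the same correlation of 0.0399 to all genes, so it does not weigh a difference between mice in these 3.

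Other splits of the arrays bear on the remaining counts. For the cerebellum, hippocampus and prefrontal cortex the splits decide nothing, since the real count was 0 and 35, 35 and 35 of 35 splits must then give as many (highest others 5, 46 and 131). For called lists, 32 of 35 splits in the amygdala gave as many (2, highest other 13), 19 in the cerebellum (2, highest other 5), 12 in the hippocampus (5, highest other 9), 34 in the prefrontal cortex (1, highest other 14), 3 in the striatum (8, highest other 9) and 77 of 100 for the average (4, highest other 12), so chance is excluded for none of them. Nor is it excluded for the variation of the genotype difference between regions (16 of 100, 6 genes, highest other 65) or for the shared change (6 of 100, 0.0389, highest other 0.110). For the regions against each other, only the real split of 100 was as large in the cerebellum (2808, highest other 1008), prefrontal cortex (781, highest other 1) and striatum (1634, highest other 0). In the amygdala (874, highest other 982) and hippocampus (885, highest other 1148) 2 of 100 were as large. Another split gave more genes there. The shuffled groups mix arrays of regions that differ, and can gain genes from those differences. The larger counts of other splits therefore do not show that chance gives as many. For the same reason these splits bear on whether regions differ at all and not on 1 region.

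The genotype difference varied between regions for Mup2 and Mup22 (adjusted p = 0.0150) and for Alb, Gabrq, Gpx3 and Mup9 (adjusted p = 0.0232). The count of 6 fell to 3 without Thr amygdala replicate 6 or 8 and to 0 without Ala striatum replicate 34 or Thr striatum replicate 40.

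Single arrays stood apart, by the gap to the nearest array as a share of the range of the group, in 32 of 454 groups tested, where chance gives about 1 in 20, or 23. In the amygdala these were Colgalt2 (0.852), Barhl2 (0.950), Dio3 (0.859) and Trh (0.909) in Thr, and the hypothalamus list in Thr (0.833). In the cerebellum they were Dio2 (0.874), Rpl3 (0.903) and Zfp976 (0.845) in Ala, and Ttr (0.969) and the choroid plexus list (0.834) in Thr. Hippocampus groups were Pcdhb3 (0.888) and Dio2 (0.883) in Ala and Cd59a (0.842) in Thr, and prefrontal cortex groups were Thra in Thr (0.851) and Ddit3 in Ala (0.835). Striatum groups in Thr were Fgg (0.835), Thra (0.834), Cyp26b1 (0.868) and Ndufb3 (0.954), and in Ala they were Hr (0.909), Nts (0.835), Homer1 (0.831), Ndufb3 (0.835), Sdha (0.877), Ramp3 (0.912) and Calb2 (0.886). Over the 8 arrays of a region they were Nr2f2 in the amygdala (0.575), Lmo3 (0.553), Chrm1 (0.614) and Nrgn (0.596) in the cerebellum, and Rgs9 (0.581) and Drd1 (0.575) in the striatum.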

How the results depend on the processing

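The liver score, the thalamus score, omitting the 2 farthest arrays of a region and low against high label numbers of each group as a covariate were chosen after seeing the data; the other alternatives were fixed before the data were examined. Of the comparisons of named genes with alternatives, 6703 kept their side of the threshold, of which 6626 kept the sign and 77, uncalled under both settings, did not, while 119 lost the call, 19 gained it and 0 called values changed sign. For lists, 481 kept side and sign, 92 lost the call, 0 gained it and 5 changed sign. No paired analysis was possible because the groups share no replicate numbers, and the fit with place in label order as a random block only explores a link that the labels do not give. A list adjusted for its own score gives no value by construction. Signals near the negative controls limit what dim genes can show, and for the values that follow the cause was not tested, except that fewer genes are tested under a stricter filter and that the liver score holds called genes. Without a filter 7 lists were called in the average, and with a stricter filter 11 genes in the amygdala, 7 in the striatum and 1 list in the amygdala. With every probe set the average had 6 calls and the interaction 12, and with robust eBayes the interaction had 0. At an unadjusted p under 0.05 the counts were 798 in the amygdala, 291 in the cerebellum, 471 in the hippocampus, 349 in the prefrontal cortex, 920 in the striatum, 804 in the average, 401 for the interaction and 5 near Dio2. A region fitted alone gave 5 genes in the amygdala and 7 in the striatum, and the choroid plexus score as a covariate gave 7 in the striatum and 0 for the interaction. With an estimated correlation 0 lists were called in the cerebellum, hippocampus, prefrontal cortex and striatum and 2 in the average, with fry 0, 0, 0, 1 and 2, and with camera on ranks 0 in the amygdala. Without the cerebellum the interaction had 3 calls and without the striatum 0. At an absolute log2 difference of at least 2 the regions had 153 (amygdala), 1039 (cerebellum), 211 (hippocampus), 159 (prefrontal cortex) and 448 (striatum) genes.

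Leaving out 1 array at a time, counts of genes ran from 6 to 20 in the amygdala, 0 to 3 in the hippocampus, 7 to 12 in the striatum and 0 to 8 for the interaction. Counts of lists ran from 2 to 11 in the amygdala, 2 to 4 in the cerebellum, 3 to 9 in the hippocampus, 0 to 3 in the prefrontal cortex, 3 to 10 in the striatum and 3 to 8 in the average. The mean differences in the striatum ran from -0.24 to 0.03 for oxidative phosphorylation and from -0.41 to 0.04 for ribosomal proteins, above 0 without Thr striatum replicate 37.

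The liver score as a covariate gave 0 genes in the striatum, 0 for the interaction, and 5 lists in the striatum and 7 in the average, and the thalamus score gave 19 genes in the striatum. Omitting the 2 farthest arrays gave 4 genes and 7 lists in the amygdala and 7 lists in the average (amygdala arrays), 2 interaction genes and 1 list in the cerebellum (cerebellum arrays), 8 lists in the hippocampus (hippocampus arrays) and 0 interaction genes (striatum arrays). Mean differences that turned positive were those of ribosomal proteins in the prefrontal cortex (0.0968) and of oxidative phosphorylation (0.0386) and ribosomal proteins (0.114) in the striatum when the 2 farthest arrays of the region were omitted, and of the latter lists without Thr striatum replicate 37 (0.0281 and 0.0396).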

Other observations

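The tests of a shared place and of a processing run were chosen after the results were seen.

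The prefrontal cortex arrays carried genes of the olfactory bulb. Eomes, a transcription factor of bulb projection neurons, was higher than in the other regions by 3.51 ± 0.32 (SE), Shisa3 by 1.77 ± 0.19, Synpr by 1.94 ± 0.21 and Tbx21 by 1.02 ± 0.14, while Trhr and Slc17a6 differed by 0.19 ± 0.28 and 0.12 ± 0.43. Tbx21 in every region, and Eomes and Shisa3 on average over the other regions, lay below the range of the negative control medians, so the sizes of their differences depend on the background. The score of the olfactory bulb markers ran from -1.10 in Ala prefrontal cortex replicate 26 to 1.13 in Ala replicate 27. Immediate early genes were also higher there, 9 of 22 past the threshold, with Npas4 at 1.81 ± 0.41, Arc at 1.39 ± 0.31 and Fosb at 1.21 ± 0.20. The prefrontal cortex was not alone in this, as the striatum had 8 of 22 higher and 3 lower. The cerebellum, part of the mean compared against, had 15 of 22 lower and 3 higher. The genes of this paragraph were named after their values were seen.

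Ttr, which choroid plexus expresses at a high level, varied widely between arrays of a group. Its log2 signal was 17.60, 7.58, 17.45 and 6.07 in Ala cerebellum replicates 9 to 12, and 16.93 in Ala amygdala replicate 2 against 5.70 in replicate 4.

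Arrays with the same place in the order of label numbers within their group deviated together across regions. The mean residual correlation across genes was 0.0667 over 80 same-place pairs and -0.0223 over 240 other pairs, a difference of 0.0890 (permutation test, one-sided, p = 1e-04, the smallest these permutations can give). A mouse that gave the arrays of a place may be behind this, which the labels do not state. Same-place arrays also always share low or high label numbers. That difference was not removed before the test, so the test cannot tell it apart from a shared mouse. Immediate early genes were low in the second Ala array of all 5 regions, with a mean score of -0.89. The first Ala arrays also have low label numbers, but their mean score was 0.44. It was below the mean of the region in 0 of 5 regions. For this list, low against high label numbers alone is therefore argued against. The list was picked after its values were seen, and the labels do not say what the arrays of a place share. The consensus correlation with place as a block was 0.0399.

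The split of the 35 with the most calls, 1262 genes, set the 2 lowest against the 2 highest label numbers in both genotypes, led by Rps21, Rpl36 and H4c4. The ribosomal protein list differed the same way in 10 of 10 groups, by 0.05 to 0.87, but the split was picked for its calls and ribosomal genes are among the first of them, so this does not test whether a processing run was shared across groups. That structure crosses genotype evenly, and with it as a covariate the calls were 20 in the amygdala, 12 in the striatum, 4 in the average (Entpd4 added, adjusted p = 0.000164) and 7 for the interaction.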
